A study of Mus musculus with 12 samples.

How the data were processed

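Leukocytes (CD45+) were sorted from the meninges and from the brain parenchyma of mice with the 5xFAD transgenes and of mice without them, and receptor libraries were made with the Chromium Single Cell Immune Profiling v2 kit, per the labels' protocols. This kit tags every cDNA with a cell barcode and a unique molecular identifier (UMI) and enriches the T cell receptor chains by PCR. The 6 receptor libraries entered the analysis. The 6 matching gene expression samples were not analysed here, so cell types such as CD8+ T cells could not be read from transcripts, and iNKT-like and MAIT-like cells were named from their receptors alone.

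The deposited files list, for every contig assembled in a cell, its V, D, J and C genes, CDR3 sequences, productive status and clonotype identifier, together with raw counts of reads and UMIs that carry no normalization, per the file headers. Per the submitters' processing notes, Cell Ranger 6.0 and the mouse build mm10 were used. The notes give no further steps, and the filters behind the contig lists are not given in the sources used here. All listed productive contigs were full length. The cells are those the deposited files list.

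From the productive contigs, cells with exactly 1 TRB and at least 1 TRA chain were kept, and cells with 2 or more TRB (431 of 7056 cells with a productive chain over all libraries), which can be doublets, without TRB (230) or without TRA (1222) were left out of clonotypes. No other doublet filter was run. A clonotype was the CDR3 nucleotide sequence of the TRB and of the TRA with most UMIs. Since the number of repeated clonotypes grows with the cells sampled, the expanded share, the share of the 10 largest clonotypes and clonality (1 minus normalised Shannon entropy) were averaged over 1000 random draws of as many cells as the smallest library compared. Drawing was tested on a simulated repertoire, where it gave 135 clonotypes for 135 expected. In paired cells TRA had a median of 34 to 75 UMIs and TRB of 8 to 9, over the libraries. Shares of single libraries carry 95% exact binomial (Clopper-Pearson) intervals, and beside a count of 0 the text gives the limit of 3 counts, while the figures keep the exact interval. Both cover counting error only.

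Group means were compared with two-sided exact permutation tests over libraries (smallest possible p 0.333 for 2 against 2 and 0.133 for 2 against 4), and expanded with 1-cell clonotypes by an exact sign-flip test over the 6 libraries (smallest 0.0312). Benjamini-Hochberg adjustment ran over the 10 values of each comparison of libraries and over the 2 CDR3 lengths of the expansion comparison. V and J use was counted as clonotypes per segment and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with the number of clonotypes as library size, segments of at least 10 clonotypes, near-identical D and N copies of TRAV segments collapsed and an adjusted p threshold of 0.05. Tissue was tested with genotype as covariate and expansion with library as block. Standard errors were taken as the log2 fold change divided by the root of the F statistic. The fits were tested on simulated counts with 20 changed segments of at least 40 clonotypes each. The spread of the simulated counts was set by hand and not estimated from the data. For expansion 5 of 10 segments changed 4-fold and 2 of 10 changed 2-fold were recovered, and the genotype fit made 1 false call. Segment positions came from GENCODE M21 (GRCm38, the assembly named mm10), where the collapsed TRAV names take the position of the copy without a letter. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

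Before the data were examined, the comparisons, tests, receptor definitions, segment lists and the rule for named segments were fixed: every segment past the threshold, the 5 TRBV, 5 TRAV, 3 TRBJ and 3 TRAJ segments with most clonotypes, the 3 with the smallest p in each direction, for the meninges the 3 with the largest difference each way, the 3 largest clonotypes of a library and up to 10 shared ones. Alternatives fixed with them were the deposited clonotype identifier (over all cells with a productive chain), TRB alone (over all cells with 1 TRB), amino acid sequences, at least 2 UMIs per chain, no thinning, expansion from 3 cells, cells in place of clonotypes, TRAV copies kept apart, TMM factors, DESeq2 1.42.0, no count filter, the replicate number as block and each parenchyma library left out (each library for expansion). Leaving out a meninges library in the tissue comparison, leaving out iNKT-like receptors, using the deposited identifier or TRB alone over paired cells and merging the joint TRBV12-2+TRBV13-2 label were added after the data were seen.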

Results

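Paired T cell receptor chains were sequenced from sorted CD45+ immune cells of the brain parenchyma and of the meninges, the membranes around the brain, of 5xFADTg and NonTg C57BL/6 mice. The 5xFAD line carries mutant human amyloid precursor protein and presenilin transgenes, builds up amyloid plaques and serves as a model of Alzheimer's disease. NonTg mice lack the transgenes. There were 6 receptor libraries, of which 4 came from parenchyma (2 NonTg and 2 5xFADTg) and 2 from meninges (1 of each genotype). The labels name no animals, so the spread between libraries may be technical in part. Each library held 15827899 to 26710709 reads over its listed contigs, and 49997 to 128700 UMIs. Between 425 and 2122 cells per library had a productive chain. Between 349 and 1453 of these had exactly 1 productive beta chain (TRB) and at least 1 alpha chain (TRA), and 5207 such paired cells made up 3108 clonotypes, counted per library. A clonotype was a TRA and TRB pair of CDR3 nucleotide sequences, CDR3 being the hypervariable loop that contacts antigen. A clonotype of 2 or more cells is called expanded. No library held a gamma or delta chain (TRG or TRD) or an immunoglobulin contig. Since receptor chains were enriched by PCR, this does not show that gamma-delta T cells or B cells were absent from the sorted cells.

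The first comparison asked whether parenchymal T cells of 5xFADTg mice were more clonally expanded or used other receptors than those of NonTg mice. In both genotypes close to equal parts of the parenchymal T cells belonged to expanded clonotypes and to clonotypes of 1 cell. At 766 cells per library, expanded clonotypes held 49.6% ± 0.234 of the cells in 5xFADTg and 49.4% ± 0.272 in NonTg (SD, n = 2 each), a difference of 0.181 percentage points (two-sided exact permutation p = 0.667, where the smallest possible is 0.333). The 10 largest clonotypes held 28.0% ± 3.98 of the cells in 5xFADTg and 27.6% ± 6.94 in NonTg (exact permutation p = 1, n = 2 each). Clonality, which is 0 when all clonotypes are of equal size and approaches 1 when few hold all cells, was 0.104 ± 0.0131 against 0.110 ± 0.0384 (exact permutation p = 1, n = 2 each). Without equalising the cell numbers, the difference in expanded share was 3.52 percentage points, since the 5xFADTg libraries held more cells. With equalised numbers it was 2.23 points by the deposited clonotype identifier over all cells with a productive chain, and 1.58 points by TRB alone over all cells with 1 TRB, which adds those without TRA (exact permutation p = 0.333 for these 3 differences, the smallest possible). Over paired cells only, alternatives added after the data were seen, the same identifiers gave -0.173 and 0.0325 points (exact permutation p = 1 and 0.667), so the larger differences came with the added cells. The unequalised shares were 51.6% (95% exact binomial interval 48.5 to 54.6%) and 49.6% (46.0 to 53.2%) in the NonTg libraries, and 53.2% (50.3 to 56.0%) and 55.1% (52.5 to 57.6%) in the 5xFADTg libraries. Such intervals cover counting error only.

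The largest parenchymal clones differed in every library and none was found in both libraries of a genotype. NonTg library 2 held the most dominant clonotype, 94 cells or 12.3% of its paired cells, with the beta chain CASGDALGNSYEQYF and the alpha chain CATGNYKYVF of TRAV8N-2 and TRAJ40. It was followed there by a clonotype of 66 cells with TRBV19 (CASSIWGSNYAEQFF) and TRAV6-5 (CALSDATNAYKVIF). In NonTg library 1 the largest clonotype had 39 cells (TRBV10, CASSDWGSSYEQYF). GENCODE M21 lists TRBV10 as a pseudogene, and this V label of the deposited files was not checked further. In 5xFADTg library 1 the largest clonotype had 71 cells (TRBV1, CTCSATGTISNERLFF) and in 5xFADTg library 2 it had 85 cells (TRBV1, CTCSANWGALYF). These sizes count paired cells only. Over all cells with 1 TRB, with or without TRA, the TRBV17 sequence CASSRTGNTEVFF reached 86 cells in 5xFADTg library 1. In 5xFADTg library 2, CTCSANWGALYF reached 115 such cells and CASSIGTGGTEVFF 107.

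Receptors of invariant natural killer T (iNKT) cells, which recognise lipids presented by CD1d, made up a higher share in both 5xFADTg parenchyma libraries than in both NonTg libraries. These iNKT-like receptors joined TRAV11 to TRAJ18 with an alpha CDR3 of 15 amino acids. They formed 5.50% ± 1.96 of clonotypes in 5xFADTg and 2.88% ± 0.338 in NonTg (SD, n = 2 each), a difference of 2.62 percentage points with the smallest p the design allows (exact permutation p = 0.333, Benjamini-Hochberg adjusted p = 1 over 10 comparisons). The libraries stood at 2.64% (95% exact interval 1.52 to 4.25%) and 3.12% (1.71 to 5.18%) in NonTg, and at 4.11% (2.73 to 5.92%) and 6.89% (5.22 to 8.89%) in 5xFADTg, so the intervals of neighbouring libraries overlapped. Without 5xFADTg library 2 the difference was 1.23 points, and without 5xFADTg library 1 it was 4.01 points. Over cells, the shares were 1.51% and 1.83% in NonTg and 4.64% and 3.85% in 5xFADTg. In 5xFADTg library 1, 30 of the 56 iNKT-like cells belonged to a clonotype with TRBV13-3 (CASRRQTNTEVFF), while the other parenchyma libraries held no iNKT-like clonotype above 2 cells. Of all 165 iNKT-like clonotypes, 155 (93.9%, 95% exact interval 89.1 to 97.1%) used a TRBV segment usual for iNKT cells (TRBV13-1, TRBV13-2, TRBV13-3, TRBV29 or TRBV1), against 33.9% of the other clonotypes. The joint label TRBV12-2+TRBV13-2, which names both genes, was counted as TRBV13-2 in such shares. The alpha sequence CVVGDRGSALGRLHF accounted for 157 of the 165.

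**Figure D1:**
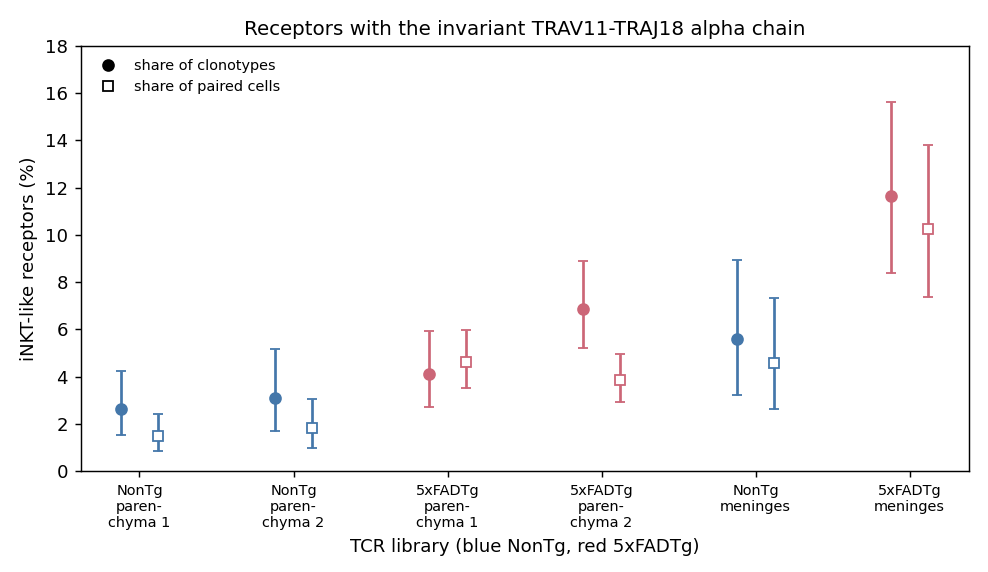
Share of iNKT-like receptors (vertical axis, %) in each of the 6 receptor libraries (horizontal axis), over clonotypes (filled circles) and over paired cells (open squares), with 95% exact binomial intervals for counting error only. By clonotypes the NonTg parenchyma libraries sit at 2.64% and 3.12%, the 5xFADTg parenchyma libraries at 4.11% and 6.89%, and the meninges libraries at 5.59% (NonTg) and 11.7% (5xFADTg).

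Receptors of mucosal-associated invariant T (MAIT) cells, which recognise vitamin B metabolites on MR1, were rare in parenchyma. MAIT-like receptors (TRAV1 with TRAJ33 and an alpha CDR3 of 12 amino acids) formed 0.751% ± 0.201 of 5xFADTg and 0.940% ± 0.0702 of NonTg clonotypes (exact permutation p = 0.667, n = 2 each). Of the 23 MAIT-like clonotypes in all libraries, 18 used TRBV13-1, TRBV13-2, TRBV13-3 or TRBV19, the list fixed for MAIT cells (78.3%, 95% exact interval 56.3 to 92.5%), against 33.3% of other clonotypes. Cells with an additional productive TRA chain, which arises when both TRA alleles rearrange, were 8.43% ± 0.435 in 5xFADTg and 9.36% ± 0.604 in NonTg (exact permutation p = 0.333, n = 2 each). Segments of the TRBJ1 cluster were used by 35.3% ± 1.88 and 33.6% ± 1.03 of clonotypes (exact permutation p = 0.667, n = 2 each), and TRAJ61 to TRAJ31, which lie nearest to the V segments, by 45.8% ± 2.57 and 47.5% ± 5.70 (exact permutation p = 1, n = 2 each). Mean CDR3 length was 14.0 amino acids for TRB in both genotypes, and 13.7 and 13.6 amino acids for TRA (exact permutation p = 1 for both, n = 2 each). Over cells, where a large clone counts with all its cells, TRBJ1 use was 44.0% and 38.9% in the 5xFADTg libraries and 33.1% and 24.5% in the NonTg libraries, a difference of 12.6 percentage points against 1.71 by clonotypes (exact permutation p = 0.333 over cells, the smallest possible). The difference in TRB length was -0.172 amino acids over cells and -0.00925 by clonotypes (exact permutation p = 0.333 and 1), and in TRA length 0.230 and 0.0793 (exact permutation p = 0.667 and 1).

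V and J segment use did not separate the genotypes in parenchyma. Of 118 segments tested, edgeR's quasi-likelihood test called 0 at an adjusted p of 0.05, with 6 at an unadjusted p under 0.05 and 0 by DESeq2 at either level. The nearest in the higher direction were TRAJ5 (log2 fold change 1.59, SE 0.61), TRAV11 (0.94, SE 0.37) and TRBV29 (0.69, SE 0.33), and in the lower direction TRAV6-5 (-0.96, SE 0.31), TRAJ57 (-1.05, SE 0.36) and TRAJ6 (-1.06, SE 0.37), with edgeR adjusted p-values of 0.794 for all but TRBV29 (0.885). Counted over cells, TRAV6-5 passed with edgeR (log2 fold change -2.85, adjusted p = 0.0323). That count holds the 66-cell TRAV6-5 clonotype of NonTg library 2. With copies collapsed it also holds a 33-cell TRAV6D-5 clonotype of NonTg library 1 (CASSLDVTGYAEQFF). TRAV6-5 lies on chromosome 14, 53491115 to 53491622 (mm10). The most used segments, among them TRBV3, TRBV13-3, TRBV19, TRAV3-3, TRAV12-2, TRAV16, TRBJ2-7 and TRAJ22, had edgeR adjusted p-values of 0.794 to 0.998. None of the 6 segment lists (TRBJ1 and TRBJ2 clusters, both parts of the TRAJ locus, and the TRBV segments of iNKT and MAIT receptors) held a call, either over all segments or adjusted over the list alone. In these lists, here and below, TRBV13-2 stands without the joint label. On simulated counts this test recovered 9 of 10 segments changed 4-fold and 4 of 10 changed 2-fold. The changed segments had at least 40 clonotypes, so recovery of rarer ones was not measured. Over cells, TRAJ57 had the opposite direction (log2 fold change 1.16, edgeR adjusted p = 0.616).

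The next comparison set the meninges against the parenchyma. In both genotypes a smaller share of meningeal than of parenchymal T cells belonged to expanded clonotypes, with a p at the limit of the design. At 349 cells per library, expanded clonotypes held 26.4% of cells in NonTg and 16.4% in 5xFADTg meninges, against 42.6% ± 0.0731 in NonTg and 43.2% ± 1.10 in 5xFADTg parenchyma (SD, n = 2 each). Over both genotypes this was 21.4% ± 7.05 (n = 2) against 42.9% ± 0.736 (n = 4), and both meninges libraries lay below all 4 parenchyma libraries, which gives the smallest p this design allows (exact permutation p = 0.133, adjusted p = 0.444 over 10 comparisons). The permutation test and the segment fit below take the libraries as independent. Yet each meninges library shared clonotypes with both parenchyma libraries of its genotype (47 and 19 for NonTg, 26 and 18 for 5xFADTg). Neither test uses this matching. The 10 largest clonotypes held 13.2% ± 0.835 of meningeal and 28.5% ± 4.45 of parenchymal cells (exact permutation p = 0.133, n = 2 and 4). Clonality was 0.0218 ± 0.000980 and 0.0805 ± 0.0241 (exact permutation p = 0.133, n = 2 and 4). With all cells kept, 26.4% (95% exact interval 21.8 to 31.3%) of NonTg and 16.8% (13.1 to 21.0%) of 5xFADTg meningeal cells were in expanded clonotypes.

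**Figure D2:**
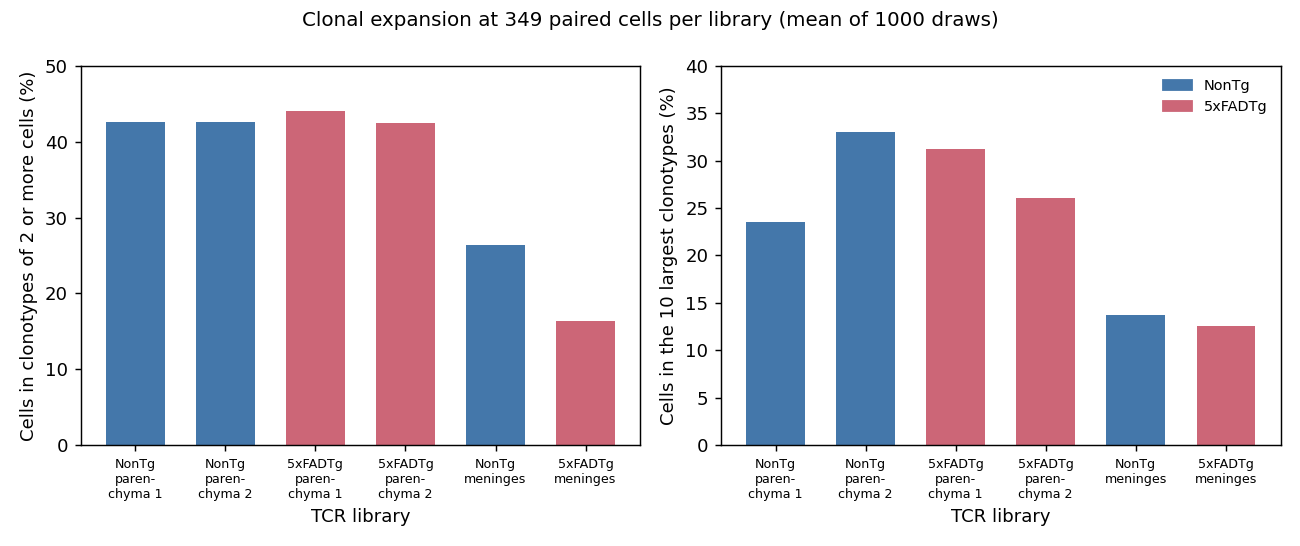
Percentage of paired cells in clonotypes of 2 or more cells (left) and in the 10 largest clonotypes (right) for each of the 6 receptor libraries, each thinned to 349 cells and averaged over 1000 draws. Bars are single libraries, blue for NonTg and red for 5xFADTg. The 4 parenchyma libraries reach 42.4 to 44.0% in the left panel and the meninges libraries 26.4% and 16.4%.

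The share of iNKT-like clonotypes was 8.63% ± 4.29 in meninges (n = 2) and 4.19% ± 1.90 in parenchyma (n = 4), with overlapping libraries (exact permutation p = 0.267). The difference of 4.44 points over both genotypes was 1.41 points without 5xFADTg meninges and 7.47 points without NonTg meninges, alternatives added after the data were seen. Both alternatives set the meninges of 1 genotype against the parenchyma of both. MAIT-like clonotypes were 0.350% ± 0.494 against 0.846% ± 0.165 (exact permutation p = 0.267, n = 2 and 4), with 0 of 326 in 5xFADTg meninges, which allows a share of up to 0.920%. That difference of -0.496 points was -0.146 without 5xFADTg meninges and -0.846 without NonTg meninges. Additional TRA chains (9.65% ± 2.56 against 8.90% ± 0.688 of cells), TRBJ1 use (35.0% ± 3.47 against 34.4% ± 1.58), TRAJ61 to TRAJ31 use (46.2% ± 2.88 against 46.6% ± 3.73) and mean TRB and TRA CDR3 length (14.1 against 14.0 and 13.7 against 13.7 amino acids) had exact permutation p-values of 0.533 to 0.933 (n = 2 and 4).

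With genotype as a covariate, edgeR called 0 of 120 segments between meninges and parenchyma, with 7 at an unadjusted p under 0.05, and DESeq2 called 0, with 1 at an unadjusted p under 0.05. The largest evidence was for the iNKT segments TRAV11, used by 8.63% ± 4.29 of meningeal and 4.41% ± 2.06 of parenchymal clonotypes (log2 fold change 0.95, SE 0.26, edgeR adjusted p = 0.252), and TRAJ18 (0.80, SE 0.25, edgeR adjusted p = 0.324). Both passed with edgeR when each chain had at least 2 UMIs (TRAV11 adjusted p = 0.0214 and TRAJ18 adjusted p = 0.0349). TRAJ9 followed in the higher direction (0.76), and TRAV3-3 (-0.69), TRAJ53 (-1.69) and TRAJ40 (-0.97) in the lower, each with an edgeR adjusted p of 0.642. TRAV11 lies on chromosome 14 from 53519303 to 53519859 and TRAJ18 from 54200777 to 54200842 (mm10), both on the forward strand of the alpha locus. No segment list held a call over all segments or adjusted over the list alone. On simulated counts, 9 of 10 segments changed 4-fold and 3 of 10 changed 2-fold were recovered, again among segments of at least 40 clonotypes.

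Meninges and parenchyma of the same genotype shared clonotypes. By identical TRA and TRB nucleotide sequences there were 110 shared pairs over the 4 library pairs that joined meninges and parenchyma of a genotype: 47 and 19 for NonTg parenchyma 1 and 2, and 26 and 18 for 5xFADTg parenchyma 1 and 2. Libraries of different genotype shared 1 over 9 library pairs, and the replicate parenchyma libraries of a genotype shared 0 over 2. Of the NonTg meningeal clonotypes, 23.1% (66 of 286, 95% exact interval 18.3 to 28.4%) were also found in NonTg parenchyma, and they held 34.7% of the meningeal cells. Of the 5xFADTg meningeal clonotypes, 13.5% (44 of 326, 10.0 to 17.7%) were also in 5xFADTg parenchyma, and they held 21.1% of the cells. In the parenchyma of the other genotype the numbers were 1 of 286 and 0 of 326, the latter allowing up to 0.920%.

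Clones of all size classes in parenchyma were found in meninges. Of the parenchymal clonotypes of 1 cell, 0.766 to 3.11% were also in the meninges of that genotype, of those with 2 to 4 cells 8.16 to 21.2%, of those with 5 to 9 cells from 0 of 15 to 2 of 5 and of those with 10 or more cells 27.8 to 80.0%. The 0 of 15 was that of 5xFADTg parenchyma 2 (a count of 0 allows up to 3 of 15), so the share did not rise at every step in that library. A clone with more cells has more chances to be sampled in both tissues, so a higher share among large clones is not evidence of a property of such clones. Among the clonotypes found in both tissues, those with most cells were the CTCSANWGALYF clone (85 cells in 5xFADTg parenchyma 2 and 14 in meninges), the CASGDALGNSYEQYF clone (94 in NonTg parenchyma 2 and 5 in meninges), the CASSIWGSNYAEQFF clone (66 and 4 for the same libraries) and the TRBV17 clone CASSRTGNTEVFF (64 in 5xFADTg parenchyma 1 and 4 in meninges). The TRBV29 clone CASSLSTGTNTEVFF had 38 cells in 5xFADTg parenchyma 1 and 9 in meninges. Other large clones were absent from the meningeal cells sampled, among them the 71-cell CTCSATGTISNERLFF clone of 5xFADTg parenchyma 1 and the 69-cell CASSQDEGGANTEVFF clone of 5xFADTg parenchyma 2. In all, 111 nucleotide pairs were in 2 libraries and 0 in 3 or more, and 1 of the 111 was iNKT-like.

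**Figure D3:**
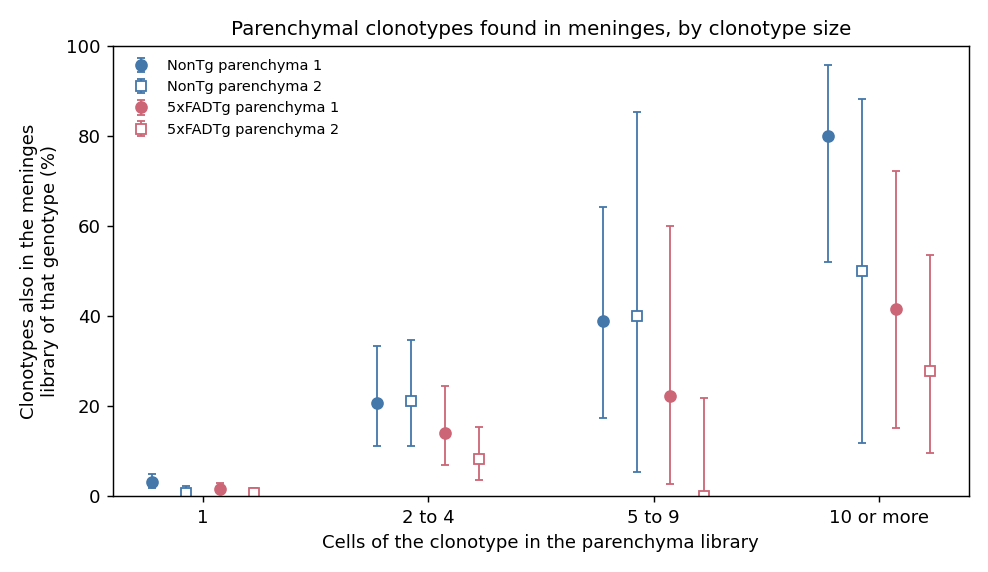
Percentage of the clonotypes of each parenchyma library that were also found in the meninges library of that genotype (vertical axis), by the number of cells the clonotype had in parenchyma (horizontal axis), with 95% exact binomial intervals. The shares lie at 0.766 to 3.11% for clonotypes of 1 cell and at 27.8 to 80.0% for clonotypes of 10 or more cells.

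Within each library, expanded clonotypes were set against clonotypes of 1 cell to see which segments differed between them. Size was taken per library, so a clone found in both tissues counts in each. A meningeal clonotype of 1 cell can thus be a large parenchymal clone. The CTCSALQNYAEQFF clone, for example, had 29 cells in NonTg parenchyma 1 and 1 in NonTg meninges. The iNKT segments TRAV11 and TRAJ18 were lower among expanded clonotypes. TRAV11 was used by 3 of 424 expanded clonotypes (0.708%) and by 168 of 2684 clonotypes of 1 cell (6.26%), a ratio of 0.113 (95% counting interval 0.0231 to 0.336). It was lower among the expanded in 6 of 6 libraries, where the expanded share averaged 0.436% ± 0.689 and the other 6.49% ± 3.44 (SD, n = 6), and passed with edgeR (adjusted p = 2.29e-05). The expanded counts were 0 of 91 and 0 of 63 in NonTg parenchyma, and 1 of 92 and 2 of 131 in 5xFADTg parenchyma. In the meninges they were 0 of 29 (NonTg) and 0 of 18 (5xFADTg). A count of 0 allows up to 3, so single meninges libraries say little. TRAJ18 was used by 9 expanded clonotypes (2.12%) against 7.34% (log2 fold change -1.70, SE 0.39, edgeR adjusted p = 0.00161), and it was lower in 5 of 6 libraries. Of the iNKT-like receptors themselves, 3 were expanded and 162 were of 1 cell, a ratio of 0.117 (95% counting interval 0.0239 to 0.349) between the shares of 0.708% and 6.04%. TRBV13-2 was the remaining call (edgeR adjusted p = 0.0202), at 0 of 424 expanded clonotypes and 52 of 2684 others (1.94%), or at least 2.74-fold lower against a floor of 3 clonotypes over all libraries, a floor that leaves out the counting error of the 52 (95% counting interval of the ratio up to 0.465). In the files most chains of this gene carry the joint label TRBV12-2+TRBV13-2, 9 expanded clonotypes held cells of both labels, and a clonotype takes the label of most of its cells. With the labels merged, an alternative added after the data were seen, TRBV13-2 did not pass (log2 fold change -0.75, edgeR adjusted p = 0.0788). TRBV12-2 and TRBV13-2 are neighbours on chromosome 6, at 41118851 to 41119364 and 41121396 to 41121832 (mm10).

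No segment was called higher among the expanded of the 120 tested by edgeR, with 13 at an unadjusted p under 0.05 in either direction, and DESeq2 called TRAV11 alone, with 8 unadjusted. The 3 segments nearest to a call in the higher direction were TRAV5-1 (log2 fold change 1.75, SE 0.61, edgeR adjusted p = 0.110), TRBV3 (0.67, SE 0.21, edgeR adjusted p = 0.110, higher in 6 of 6 libraries) and TRAJ26 (0.87, SE 0.34, edgeR adjusted p = 0.199, higher in 6 of 6). By list, the TRBV segments of iNKT receptors held 1 call of 5 tested over all segments and 1 adjusted over the list alone (TRBV13-2). Those of MAIT receptors held 1 of 4 and 2 adjusted over the list alone (TRBV13-2 and TRBV13-1). Both of these TRBV lists took TRBV13-2 by its own name (52 clonotypes) and left out the joint label (338 clonotypes). Their TRBV13-2 calls thus rest on a name that did not pass once the labels were merged. TRAJ30 to TRAJ2 held 1 of 21 by both counts (TRAJ18), and the other 3 lists held 0. DESeq2 kept TRAV11 as a call and lost TRAJ18 (adjusted p = 0.0810) and TRBV13-2 (adjusted p = 0.113), as did leaving out 5xFADTg parenchyma 2, where the edgeR adjusted p was 0.0668 for TRAJ18 and 0.150 for TRBV13-2. TRBV13-2 was also lost without either NonTg parenchyma library (edgeR adjusted p = 0.140 and 0.104), with at least 2 UMIs per chain (0.0578), with expansion from 3 cells (0.132) and without iNKT-like clonotypes (0.0977). TRAJ18 was also lost over cells (edgeR adjusted p = 0.190) and with expansion from 3 cells (0.0700), and with iNKT-like clonotypes left out TRAJ18 had a log2 fold change of 0.00 (edgeR adjusted p = 0.999). TRA CDR3 was 0.151 amino acids shorter in expanded clonotypes (13.6 ± 0.109 against 13.7 ± 0.0842, n = 6, shorter in 5 of 6 libraries), which did not pass (exact sign-flip permutation p = 0.0625, where the smallest possible is 0.0312). For TRB the difference was 0.123 amino acids (14.1 ± 0.307 against 14.0 ± 0.0894, exact sign-flip permutation p = 0.562, n = 6), and -0.00627 without NonTg meninges.

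**Figure D4:**
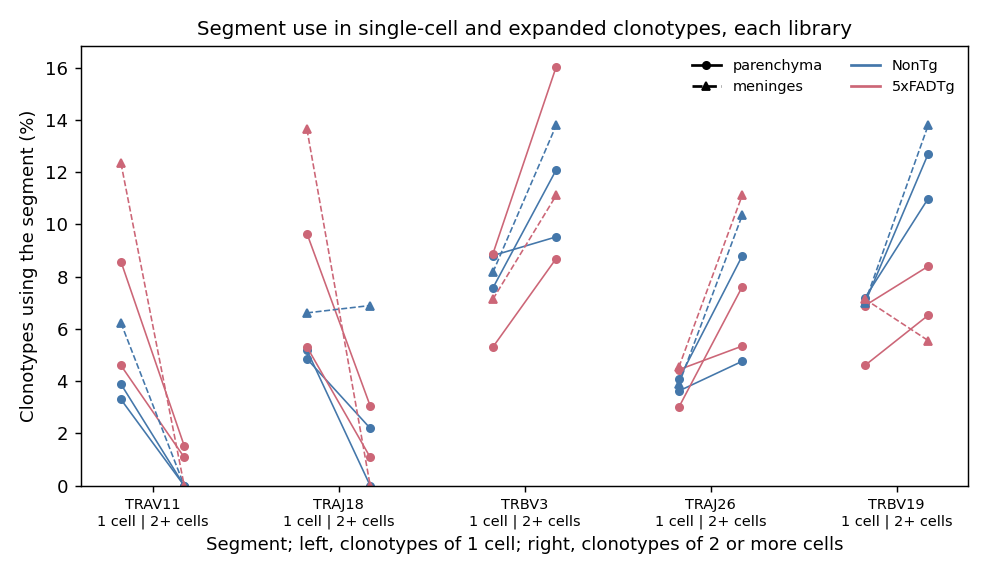
Percentage of clonotypes that used each of 5 segments (vertical axis) among clonotypes of 1 cell (left point) and of 2 or more cells (right point), with 1 line per library, solid for parenchyma, dashed for meninges, blue for NonTg and red for 5xFADTg. TRAV11 was lower among the expanded in 6 of 6 libraries and TRAJ18 in 5 of 6, while TRBV3 and TRAJ26 were higher in 6 of 6 without passing the test.

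The meninges of the genotypes were compared as 1 library each and without a test, and intervals cover counting error only. At 349 cells, expanded clonotypes held 16.4% of 5xFADTg and 26.4% of NonTg meningeal cells, and the 10 largest clonotypes held 12.6% and 13.8%. The iNKT-like share of clonotypes was 11.7% (38 of 326, 95% exact interval 8.38 to 15.6%) in 5xFADTg and 5.59% (16 of 286, 3.23 to 8.93%) in NonTg. The segments furthest apart toward 5xFADTg were TRAJ18 (12.9% against 6.64%), TRAV11 (11.7% against 5.59%) and TRBJ1-4 (8.59% against 4.90%). Toward NonTg they were TRAV6-5 (0.920%, or 3 of 326, against 4.55%, or 13 of 286), TRBJ2-1 (7.67% against 11.2%) and TRBJ2-7 (20.2% against 23.4%). The largest meningeal clone had 14 cells in 5xFADTg (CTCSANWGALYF) and 6 in NonTg (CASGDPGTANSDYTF), and both were also in the parenchyma of that genotype.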

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

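Cells with a TRB but no productive TRA chain entered only the alternatives with the deposited identifier over all cells and with TRB alone, and among them the largest TRB clone was larger in both 5xFADTg parenchyma libraries than in NonTg parenchyma, where it reached 12 cells at most (0.835% of the cells with a productive chain). In 5xFADTg parenchyma 2 it had 105 cells (TRBV12-1 and TRBJ1-1, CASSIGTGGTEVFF), or 4.95% of the cells with a productive chain. Of the 107 cells with 1 TRB that carried this sequence, 2 had a productive TRA, and these 2 TRA differed. The clone's median TRB count was 6 UMIs, against 7 in other TRB-only cells, and 1 cell of it was found in 5xFADTg meninges. The share of cells without TRA was 22.9% in that library, against 14.5 to 16.1% in the other parenchyma libraries. Without the largest such clone of each library it was 18.9%, against 13.3 to 15.4%. In 5xFADTg parenchyma 1 the largest such clone had 22 cells or 1.37% (TRBV17, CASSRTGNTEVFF), and 64 further cells of it carried 1 and the same TRA. Contigs whose segments bore the names of 2 chain types mostly joined a TRDV segment to a TRAJ segment. Such contigs made up 0.156% and 0.153% of the contigs in 5xFADTg parenchyma 1 and 2, above the 0.104% of the higher NonTg parenchyma library. NonTg meninges lay above all of these with 0.247% (3 of 1217 contigs), and the counts were 1 to 9 per library. Neither difference was tested, and no explanation for either was weighed.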

How the results depend on the processing

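Leaving out iNKT-like receptors, merging the joint TRBV label, the deposited identifier or TRB alone over paired cells and leaving out a meninges library in the tissue comparison were alternatives chosen after seeing the data. Of 123 values under other settings for the compared values and counts of calls, 112 kept their direction and their side of the threshold, or, for counts, stayed within 1.5 times. Of the others, 3 counts were lower, 3 were higher and 5 values changed sign. Most tests of values could not reach 0.05 in this design, so keeping their side says little. Differences are 5xFADTg minus NonTg, meninges minus parenchyma and expanded minus 1-cell clonotypes. For genotype, clonality turned to 0.00445 with the deposited identifier over all cells, 0.00442 with TRB alone (which adds cells without TRA) and 0.00723 without thinning, expanded share to -0.173 points with the deposited identifier over paired cells, and TRAJ61 to TRAJ31 use to 0.435 points over cells. Apart from left-out libraries, the differences that kept their direction but grew more than 2.5-fold were, for genotype, expanded share (2.23 points with the deposited identifier over all cells, 1.58 with TRB alone, 3.52 without thinning), 10 largest (1.999 and 2.58 with those identifiers and cells) and, over cells, TRBJ1 (12.6 points), TRB CDR3 (-0.172 amino acids) and TRA CDR3 (0.230). Over paired cells the identifiers gave 0.588 and 0.325 points for the 10 largest and -0.00501 and -0.00809 for clonality, so that growth and that change of sign came with the added cells. For tissue such growth was seen, over cells, in TRAJ61 to TRAJ31 (-1.81 points) and TRA CDR3 (0.138 amino acids). Segment calls rose to 1 for genotype over cells (TRAV6-5) and to 2 for tissue with at least 2 UMIs per chain (TRAV11 and TRAJ18). For expansion, TMM factors gave 6 calls, all lower among the expanded, DESeq2 and expansion from 3 cells gave 1 each (TRAV11), and leaving out iNKT-like clonotypes gave 0. Counts of 2 came with cells in place of clonotypes (TRAJ18 lost), with at least 2 UMIs per chain and with the merged label (TRBV13-2 lost in both). Without iNKT-like clonotypes TRAJ18 had a log2 fold change of 0.00134, since this removes the receptors that join TRAV11 to TRAJ18. Other causes were not tested.

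With 1 library left out, genotype differences ranged from -0.0117 to 0.730 points (expanded share), -4.55 to 5.31 points (10 largest), -0.0334 to 0.0208 (clonality), -5.66 to 2.39 points (TRAJ61 to TRAJ31), -0.113 to 0.0947 amino acids (TRB CDR3) and -0.00295 to 0.162 (TRA CDR3), and kept their sign at 0.374 to 3.04 points (TRBJ1), -0.332 to -0.0476 (MAIT-like) and -1.36 to -0.504 (additional TRA). Tissue differences ranged from -2.47 to 1.61 points (TRAJ61 to TRAJ31), -1.90 to 3.002 points (TRBJ1), -1.06 to 2.56 points (additional TRA), 1.41 to 7.47 points (iNKT-like), -0.846 to -0.146 points (MAIT-like) and -0.0446 to 0.0666 amino acids (TRA CDR3). All these ends came from leaving out a meninges library. The tissue difference in TRB CDR3 ranged from 0.0381 to 0.107 amino acids (without NonTg parenchyma 2 and 1). The expansion difference ranged from -0.00627 (without NonTg meninges) to 0.176 amino acids (TRB CDR3). The expansion calls ranged from 1 (without 5xFADTg parenchyma 2) to 3, and the tissue calls stayed at 0. A lone library was assumed to vary like the others in these fits. The tissue difference in expanded share stayed between -26.6 (without NonTg meninges) and -16.5 points (without 5xFADTg meninges), and the iNKT-like genotype difference between 1.23 and 4.01 points.

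Of 506 log2 fold changes of named segments under other settings, 445 kept their direction and side, 8 lost and 6 gained a call, and 47 changed sign. For genotype these were, over cells, TRBV12-2+TRBV13-2 (-0.347), TRBV3 (0.353), TRBV13-3 (0.176), TRBV13-1 (-0.299), TRAV12-2 (0.782), TRAV6-6 (-0.0234), TRBJ2-7 (-0.517), TRBJ2-1 (-0.774), TRAJ31 (0.298) and TRAJ57 (1.16). Without iNKT-like clonotypes they were TRBV12-2+TRBV13-2 (-0.0762), TRAV12-2 (0.0317), TRBJ2-1 (-0.0186) and TRAJ18 (-0.403). TRAV12-2 turned with TMM factors (0.00609) and DESeq2 (0.0151), TRAV16 with copies kept apart (0.0854) and TRBJ2-1 with at least 2 UMIs (-0.0177). For tissue they were, over cells, TRBV12-2+TRBV13-2 (-0.00603), TRBV3 (0.0790), TRBV13-3 (0.0790), TRBV19 (-0.148) and TRAJ31 (-0.0558). Without iNKT-like clonotypes TRBV3 (0.0228), TRBJ1-1 (-0.000604) and TRAJ18 (-0.195) turned. So did TRBV13-3 with at least 2 UMIs (0.0102), TRAV16 with copies kept apart (-0.000352) and TRBJ1-1 without a count filter (-9.04e-06). For expansion they were, over cells, TRBV12-2+TRBV13-2 (0.394), TRAV3-3 (-0.140), TRAV16 (-0.106), TRAV12-2 (-1.38) and TRAJ22 (-0.134). TMM factors turned TRAV3-3 (-0.124), TRAV12-2 (-0.175), TRAV6-6 (-0.114), TRBJ2-1 (-0.0727) and TRBJ1-1 (-0.00701). DESeq2 turned TRAV3-3 (-0.117), TRAV12-2 (-0.373), TRAV6-6 (-0.0449) and TRBJ1-1 (-0.0328). Expansion from 3 cells turned TRAV16 (-0.0797) and TRAV12-2 (-0.552), and copies kept apart turned TRAV6-6 (-0.260). Apart from TRAJ18 in expansion, none of these segments was called in the reported fit or in the fit that turned it.

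With 1 library left out, log2 fold changes that crossed 0 for genotype were TRBV3 (-0.560 to 0.238), TRBV13-3 (-0.468 to 0.201), TRBV13-1 (-0.114 to 0.411), TRAV12-2 (-0.0617 to 0.0484), TRAV6-6 (-0.0170 to 0.281), TRBJ2-7 (-0.0366 to 0.135), TRBJ2-1 (-0.298 to 0.480), TRBJ1-1 (-0.0133 to 0.240) and TRAJ22 (-0.356 to 0.0339). For tissue they were TRBV3 (-0.212 to 0.166), TRBV13-3 (-0.220 to 0.100), TRBV19 (-0.0163 to 0.215), TRAV16 (-0.125 to 0.246), TRBJ1-1 (-0.0590 to 0.0725) and TRAJ31 (-0.0620 to 0.348). For expansion they were TRAV3-3 (-0.127 to 0.358), TRAV12-2 (-0.242 to 0.404) and TRAV6-6 (-0.0344 to 0.517).

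With the replicate number as block, the genotype calls stayed at 0 and the blocked differences equal the unblocked ones (expanded share 0.181 points). The numbers are only names here: over 118 segments, the replicate differences of the genotypes had a correlation of 0.127 with 2 pairs. On simulated counts, 4, 3 and 2 of 10 segments changed 2-fold were recovered for genotype, tissue and expansion, among segments of at least 40 clonotypes. The share of this due to depth was not tested.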

Other observations

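The tests of crosstalk, of mixing, of the size of the largest iNKT-like clone, of leaving out iNKT-like cells and of swaps with the merged label were chosen after their results had been seen at least in part. Identical amino acid sequences of TRB, which can arise independently in different animals, were shared 26 times over the 9 library pairs of different genotype and 7 times over the 2 pairs of replicate parenchyma libraries, while pairs of TRA and TRB nucleotide sequences were shared 1 and 0 times. The sequence pair shared between genotypes joined NonTg meninges and 5xFADTg parenchyma 2, and 0 were left there after removing barcodes present in both libraries. The 1 barcode present in both did not carry the pair in both of them.

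Meninges and parenchyma of the same genotype shared 110 nucleotide pairs. Crosstalk between libraries would carry the cell barcode along, but all 110 remained after removing barcodes present in both libraries, and 3 such barcodes were found where 3.48 were expected from the pairs of different genotype. Parenchymal cells carried evenly into the meninges samples would follow the clone sizes of parenchyma. Meningeal cells of the parenchymal clonotypes of 10 or more cells departed from those proportions in 4 of 4 parenchyma libraries (adjusted permutation p = 0.00240 to 0.0103). This argues against even carry-over as the whole cause. Carry-over that was uneven over clones or animals could also depart from them and was not tested. Independent origin in different animals is argued against. Libraries of different genotype shared 1 such pair over 9 library pairs, and replicate parenchyma libraries shared 0 over 2. Animals common to both tissues remain the candidate explanation, which the labels do not state. Carried-over cells and blood cells would need common animals too, so they concern the route. Blood cells in both samples stay open, as untested.

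The expanded share was lower in both meninges libraries than in all parenchyma libraries. Fewer cells do not account for it, since at equal cell numbers the lowest parenchyma library stayed 16.1 points above the highest meninges library. Nor do more iNKT-like cells, since the gap was 15.4 points without them. A mixture of the animals of both parenchyma libraries would lower the share, but the lower 95% bound of an equal mixture stayed at least 5.16 points above the meninges value, and over 9 mixing ratios the lowest share was 36.7% for NonTg and 37.5% for 5xFADTg. A pool of more animals than those libraries hold, and a difference between the tissues themselves, may both apply and stay open, as untested.

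The iNKT-like share was higher in 5xFADTg than in NonTg in parenchyma and, with 1 library each and no iNKT-like clonotype above 1 cell, in meninges. A single large clone is not the whole source in 5xFADTg parenchyma 2, where the largest iNKT-like clonotype held 2 of 56 iNKT-like cells and the excess over the highest NonTg parenchyma share was 29.4 cells (95% counting interval 7.16 to 49.7). In 5xFADTg parenchyma 1 it stays open, since 1 clonotype held 30 of 56 such cells and the excess was 34.0 cells (14.0 to 53.0). Without the largest iNKT-like clonotype of each library, the shares of cells were 2.21% and 3.72% in 5xFADTg parenchyma 1 and 2. In NonTg parenchyma they were 1.41% and 1.70%, and this difference was not tested. Uneven sampling of large clones was set against shares by clonotypes, where each clone counts once whatever its size. There the lowest 5xFADTg parenchyma library lay 0.992 points (-1.49 to 3.28) above the highest NonTg library. That interval spans both signs, so the counts are too few to tell the gap from counting error and the test could not decide. With 2 parenchyma libraries per genotype, chance and differences between animals remain open as well, so a higher iNKT cell share in 5xFADTg brains is a hypothesis that may merit a test in more animals.

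The calls of TRAV11, TRAJ18 and the TRBV13-2 name as lower among expanded clonotypes were set against the 32 ways of swapping the expanded and 1-cell parts within libraries. The real arrangement, with 3 calls, was the only 1 of the 32 that reached that number, and the highest of the others gave 2. That count includes TRBV13-2, whose call was lost when the joint label was merged (edgeR adjusted p = 0.0788). With the label merged the real arrangement gave 2 calls, the highest of the others also gave 2, and 2 of the 32 reached that number, so chance cannot be excluded for the number of calls. Among cells of either label, 5.56% carried TRBV13-2 alone in expanded clonotypes and 14.6% in clonotypes of 1 cell, while 0 of 424 expanded clonotypes took that name. A clonotype takes the name most of its cells carry, so the naming itself can lower this rarer name among expanded clonotypes. With the labels merged, use was lower among the expanded in each parenchyma library (6.11 to 6.59% against 12.4 to 14.5%). It was higher in both meninges libraries (13.8%, or 4 of 29, against 12.8% in NonTg, and 27.8%, or 5 of 18, against 14.0% in 5xFADTg). These expanded counts are small, and a difference between the tissues was not tested.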
